A study of Mus musculus with 4 samples.

How the data were processed

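RNA was taken from c-Kit-positive bone marrow cells selected with CD117 microbeads on an automated magnetic separator, extracted on silica columns and made into libraries by standard Illumina protocols, per the labels' protocols. Expression was quantified with kallisto and the mm10 genome build is named, per the submitters' processing notes; the version, the transcript set and the strand setting are not given in the sources used here. The deposited table holds 1 TPM value per Ensembl gene and library. The unit was inferred from the values: the 4 columns sum to between 955562 and 963135, under the total that TPM allows. kallisto shares reads among similar transcripts by an estimate, so genes with near-identical copies can lose or gain reads. TPM keeps no read counts, so depth is unknown and no counting intervals are given, and a rise in a few abundant transcripts lowers the others.

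The table holds 28987 genes, of which 27458 were given a symbol from GENCODE vM21 (GRCm38, the assembly also called mm10) by Ensembl identifier, with coordinates from the same annotation. 8906 genes were listed at 0 in all 4 libraries. An exact or near 0 can be a failed estimate: Rps12, a ribosomal protein gene, read 6.3e-07 TPM in Hif1a-intact replicate 1 and 132, 77.0 and 74.6 TPM in the others. In the text, genes with a library at 0 are therefore given per library, with no fold on those values. Annotated pseudogenes made up 20.7% and 17.7% of TPM in the Hif1a-intact libraries and 16.3% and 15.7% in the Hif1a-null libraries.

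Groups were taken from the genotype labels, 2 libraries each, with no batch or pairing named. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust off, two-sided) on log2(TPM + 1) for genes with at least 1 TPM in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are Hif1a-null minus Hif1a-intact on that scale, which understates changes of low genes. A gene under 1 TPM in both libraries of 1 group was tested only because both libraries of the other group were higher. Its direction was thus fixed by the filter. All 866 called genes had non-overlapping groups, as did 55.0% of all tested genes, where chance gives 33.3% for 2 against 2. The median log2 fold change of all tested genes was -0.06. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 20 lists. Of these, 10 passed, 0 passed with the correlation estimated from the data and 13 passed by fry. Estimating the correlation also cuts the degrees of freedom from about the number of genes to the 2 left by the libraries. Megakaryocyte markers, at an estimated correlation of 0.0092, went from an unadjusted camera p of 1.2e-11 to 0.021. Failing there thus does not by itself show that correlation between genes undid a result. The estimated correlation was above the preset for the erythroid (0.163), interferon (0.127), granulocyte (0.109) and stromal (0.0754) lists. For these the preset may make the camera p-values too small. It was below 0 for the other HIF-1 target, monocyte, B-lineage, T and NK and proliferation lists.

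The test, lists and naming rule were fixed before the data were examined. Named were Hif1a, Runx1 and Kmt2a; in each direction up to 12 genes of largest change among those past the threshold, with non-overlapping groups and at least 5 TPM on average in the higher group; and up to 4 members of smallest unadjusted p per list. Predicted genes, genes without a symbol and immunoglobulin or T cell receptor segments (88 called genes) were counted and not named. Near-identical copies were searched with blastn 2.17.0 against the annotated transcripts (at least 95% identity over at least 50% of the shorter transcript and 100 bases, either strand). Of 332 genes searched, 51 had a copy and in 15 the copies summed to more TPM than the gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

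The test was run on simulated values for the same comparison, 2 against 2, over 11582 genes with 200 changed. It called 4% of genes changed by 1 on the log2 scale, 78% of those changed by 2, 88% by 3 and 94% by 5. There were 10 false calls among 142, and 0 calls when nothing was changed. Changed genes were drawn from those with a mean log2(TPM + 1) above 2. Values were independent between genes, with the same spread in both groups. A simulated list of 20 genes shifted by 1 passed camera with the preset correlation and not with an estimated one (adjusted p = 0.214).

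Alternatives were another variance model, quantile and median-ratio rescaling, other filters and pseudocounts, abundant genes left out, each library left out in turn, and estimated correlation and fry for lists. Robust variance estimation, protein-coding genes only, and members summed with their copies were added after seeing the data. Tests made for read counts do not apply to TPM and were not run. Ahsp and Ctgf, members of 2 lists, were not analysed here. A few genes that the naming rule takes are not reported here.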

Results

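Gene expression was measured by RNA sequencing in c-Kit-positive haematopoietic stem and progenitor cells from the bone marrow of C57BL/6 mice. c-Kit (CD117) is a receptor carried by stem and progenitor cells, which were enriched on magnetic beads. The most abundant granulocyte markers averaged 46052 (Chil3), 9714 (Camp) and 9311 TPM (S100a8) over the 4 libraries. Kit averaged 119 and Cd34 220 TPM. The selection therefore does not show what share of the RNA came from stem and progenitor cells. All 4 libraries came from mice with a partial tandem duplication of Mll (Kmt2a) and a floxed Runx1 gene deleted with Mx1-Cre, a recombinase under an interferon-inducible promoter. In 2 of them (Hif1a-intact) Hif1a was not floxed, and in the other 2 (Hif1a-null by their labels) Hif1a was floxed too. Hif1a encodes the oxygen-regulated subunit of the transcription factor HIF-1. The comparison asks which transcripts differ between Mll-PTD, Runx1-deleted progenitors with and without Hif1a. Values were length-scaled relative abundances (TPM), which keep no record of sequencing depth, so the depth of each library is unknown. The labels do not say whether the libraries of a group came from separate mice, so the limma p-values measure only the spread between these samples, which may be technical. The camera p-values with the preset correlation set list members against all other genes. They do not measure the spread between samples and can be very small with few libraries. Replicate numbers only name the libraries.

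The targeted gene was not lower in the libraries labelled Hif1a-null. Hif1a (ENSMUSG00000021109, GRCm38 chromosome 12, 73901375 to 73947530, plus strand) read 87.8 ± 17.8 TPM in the Hif1a-intact group and 106 ± 10.4 TPM in the Hif1a-null group (SD, n = 2 each). Its log2 fold change was 0.28 with a standard error of 0.20 (limma, adjusted p = 0.479). A gene-level TPM includes transcript from exons outside the floxed part, so it does not check the deletion, and directions below rest on the labels. Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149, minus strand), floxed in both groups, read 75.1 ± 2.10 and 47.6 ± 1.21 TPM, a log2 fold change of -0.65 that did not pass (limma, adjusted p = 0.0636). Its libraries read 73.6 and 76.6 TPM against 48.4 and 46.7 TPM, so Runx1 was not shown to be alike in the groups. An effect of a Runx1 difference could not be told apart from one of Hif1a status. Kmt2a (ENSMUSG00000002028, chromosome 9, 44803355 to 44881296, minus strand) read 9.68 ± 0.387 and 9.40 ± 0.529 TPM (limma, adjusted p = 0.895).

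**Figure D1:**
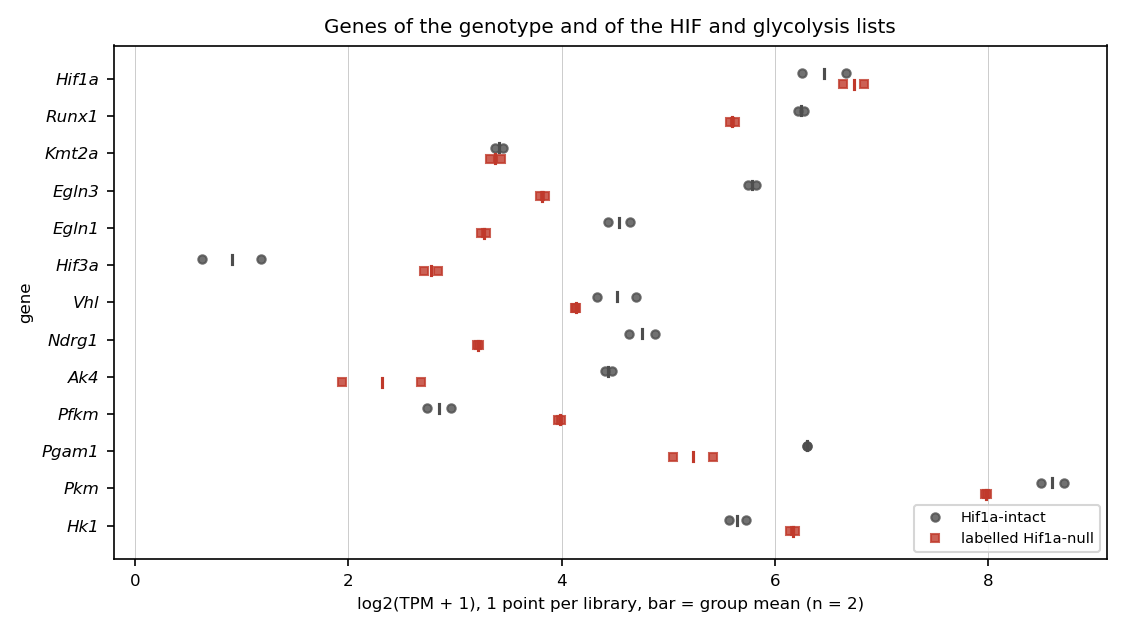
Expression of the genes of the genotype and of the named members of the HIF and glycolysis lists, as log2(TPM + 1) on the x axis, with 1 point per library (grey circles Hif1a-intact, red squares labelled Hif1a-null) and a bar at each group mean (n = 2). Hif1a overlaps between the groups, while Egln3 lies at 54.1 TPM in the Hif1a-intact group and 13.1 TPM in the Hif1a-null group.

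Libraries labelled Hif1a-null had higher globin and red cell membrane transcripts. The highest gains were in Hba-a2 (11 ± 7.87 against 1037 ± 46.6 TPM, Hif1a-intact against Hif1a-null), Hbb-bs (79.2 ± 20.7 against 5397 ± 293 TPM) and the anion exchanger Slc4a1 (1.05 ± 1.11 against 79.2 ± 0.355 TPM; SD, n = 2 each). Their log2 fold changes were 6.61, 6.10 and 5.41, with limma adjusted p of 0.00973, 0.00349 and 0.00964. Epb42 and Kel, which encode further red cell membrane proteins, rose by log2 fold changes of 5.34 and 5.22. Hba-a1, Chil1, Oxtr, Atp1b2 and Hbb-bt rose by 5.09, 5.06, 4.62, 4.42 and 4.32. Chil1 encodes a chitinase-like protein and Oxtr the oxytocin receptor. Zfp972 was listed at 0 in both Hif1a-intact libraries and read 18.6 and 27.2 TPM in the Hif1a-null libraries; summed with its near-identical copies it no longer passed, with a log2 fold change of 2.46. Hba-a1 and Hbb-bt have near-identical copies that carry most of their joint TPM, so their values are uncertain.

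The largest falls were in Hormad2, a meiotic chromosome axis gene (33.0 ± 1.30 against 0.723 ± 0.632 TPM, log2 fold change -4.35, limma adjusted p = 0.00794), and Lhx2, a LIM homeobox gene (32.6 ± 18.2 against 1.12 ± 0.0491 TPM, log2 fold change -3.87, limma adjusted p = 0.0189). Tdrd9, a germline RNA helicase of the piRNA pathway, read 14.8 and 12.6 TPM in the Hif1a-intact libraries, and 0.0504 TPM and listed at 0 in the Hif1a-null libraries. Stag3, a meiotic cohesin subunit, fell from 13.8 ± 1.37 to 1.05 ± 0.253 TPM. The neighbouring oocyte genes Oosp1 and Oosp2 on chromosome 19 (11667460 to 11691150 and 11647279 to 11660559) fell with log2 fold changes of -3.54 and -2.86. Cpa3, the mast cell carboxypeptidase, fell from 408 ± 168 to 42.4 ± 0.0595 TPM. Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 24.4 ± 4.58 to 3.85 ± 0.205 TPM (limma, adjusted p = 0.00916). Perp, Ankrd63, Ak4 and Galnt3 fell with log2 fold changes of -3.55, -3.08, -2.13 and -2.10.

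**Figure D2:**
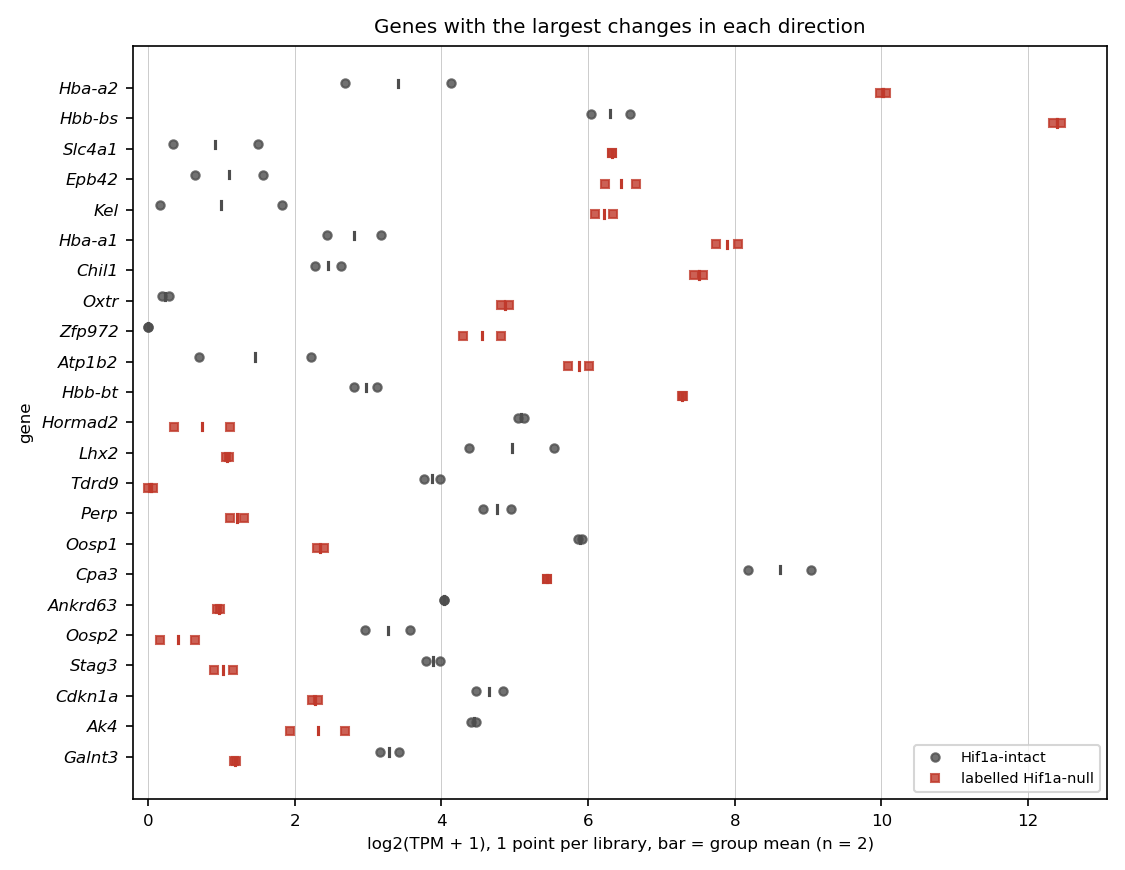
Expression of the named genes with the largest change in each direction, as log2(TPM + 1) on the x axis, with 1 point per library (grey circles Hif1a-intact, red squares labelled Hif1a-null) and a bar at each group mean (n = 2). The groups do not overlap for any of these genes, which were picked for that; Hbb-bs reaches 5397 TPM and Cpa3 drops from 408 to 42.4 TPM.

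Of 11909 genes tested, 625 were higher and 241 lower in the Hif1a-null libraries at a limma adjusted p under 0.05, and 542 and 177 of them changed at least 2-fold on the log2(TPM + 1) scale. Quantile normalization moved the split from 72.2% to 64.0% higher. That split also depends on the filter. With either Hif1a-null library left out, 535 of the 866 called genes were still tested. The others were under 1 TPM in both Hif1a-intact libraries, so they could only rise. With either Hif1a-intact library left out, 818 were still tested, and the others could only fall. Immunoglobulin and T cell receptor segments made up 0.377% and 0.262% of TPM in the Hif1a-intact libraries and 3.53% and 4.04% in the Hif1a-null libraries, and 20 segments were called higher. With either Hif1a-null library left out few or no genes passed, but the spread then came from the Hif1a-intact pair alone. That loss therefore cannot show whether the changes rested on 1 library. No called gene still tested changed sign, but this was fixed in advance, since all 866 called genes had non-overlapping groups. With either Hif1a-null library left out, 17 of the 21 erythroid members were still tested. Their median log2 fold change was 3.61 without replicate 1 and 3.53 without replicate 2. Over all 21 members and all libraries it was 3.53. Log2 values correlated across genes at r = 0.958 within the Hif1a-intact group, 0.980 within the Hif1a-null group and 0.927 to 0.934 between groups; genes are not independent replicates.

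Erythroid markers were the group with the largest change. Of 21 measured members, 17 rose, 0 fell and 4 did not pass, with 19 higher when adjusted over the list alone. Klf1, the erythroid transcription factor, rose from 0.898 ± 0.0566 to 20.3 ± 0.240 TPM (n = 2 each). Alas2, the erythroid enzyme of haem synthesis, read 0.141 ± 0.0342 and 19.7 ± 1.15 TPM, but it held 35.4% of the TPM it shares with a near-identical or overlapping annotated copy. Summed with that copy, its log2 fold change went from 4.18 to 1.0 and it no longer passed (limma, adjusted p = 0.145; 0.00151 to 0.145 over its alternatives). Megakaryocyte markers rose in 10 of 15 members, with 13 higher and 1 lower when adjusted over the list alone. They included Ppbp, a platelet chemokine (4.51 ± 1.34 against 69.5 ± 7.55 TPM), Thbs1 (2.69 ± 0.142 against 47.4 ± 0.288 TPM) and the platelet glycoprotein genes Gp5 and Gp1ba. With either Hif1a-null library left out, 17 of the 21 erythroid and 8 of the 15 megakaryocyte members were still tested. The others were under 1 TPM in both Hif1a-intact libraries, so they could only rise. Both lists passed camera with a preset correlation of 0.01 (adjusted p = 1.42e-19 and 7.98e-11). With an estimated correlation neither passed (adjusted p = 0.188 and 0.144). Without Hif1a-null replicate 1, 4 of the 17 erythroid and 1 of the 8 megakaryocyte members then tested passed, and without Hif1a-null replicate 2, 0 of the same numbers did. The list medians of log2 fold change were then 3.61 and 3.53 for erythroid and 1.67 and 1.52 for megakaryocyte markers, against 3.53 and 1.35 with all libraries, and both lists still passed camera with the preset correlation.

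Lymphoid transcripts were also higher. B-lineage markers rose in 10 of 13 members, with 12 when adjusted over the list alone. Dntt, the terminal transferase of early lymphoid cells, rose from 9.82 ± 0.578 to 188 ± 1.22 TPM, Blnk from 1.33 ± 0.109 to 17 ± 1.90 TPM, and Rag2, of the V(D)J recombinase, from 0.242 ± 0.0627 to 5.09 ± 0.270 TPM (n = 2 each). T and NK cell markers rose in 9 of 12 members, with 11 higher and 1 lower when adjusted over the list alone. Ncr1, an NK cell receptor gene, rose from 0.153 ± 0.185 to 16.7 ± 0.513 TPM, Lck from 4.55 ± 0.877 to 22.0 ± 0.0442 TPM, and Tcf7 from 0.565 ± 0.000934 to 6.72 ± 0.635 TPM. Gzma was listed at 0 in both Hif1a-intact libraries and read 4.36 and 3.02 TPM in the Hif1a-null libraries. Only 5 of the 13 B-lineage and 6 of the 12 T and NK members were still tested with either Hif1a-null library left out. The others were under 1 TPM in both Hif1a-intact libraries. They were tested only because both Hif1a-null libraries were high, so they could only rise. The camera adjusted p were 1.50e-12 and 1.07e-09, and with an estimated correlation adjusted p = 0.144 for both. Without Hif1a-null replicate 1, 1 of the 5 B-lineage and 0 of the 6 T and NK members then tested passed, and without Hif1a-null replicate 2, 0 of the same numbers did. The list medians of log2 fold change were then 1.23 and 2.09 for B-lineage and 2.08 and 1.6 for T and NK markers, against 1.96 and 1.98 with all libraries, and both lists still passed camera with the preset correlation.

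Among granulocyte markers 9 of 21 rose and 0 fell, with 10 higher and 1 lower when adjusted over the list alone. They included products of maturing neutrophils: Mmp8 rose from 3.59 ± 0.672 to 29.8 ± 0.949 TPM, Ly6g from 25.5 ± 0.876 to 146 ± 23.4 TPM, Mmp9 from 56.5 ± 5.17 to 206 ± 15.2 TPM and Retnlg from 39.3 ± 13.5 to 260 ± 11.6 TPM (n = 2 each). Monocyte, macrophage and dendritic cell markers rose in 5 and fell in 2 of 20 members, with 9 higher and 4 lower when adjusted over the list alone. Siglech, a plasmacytoid dendritic cell marker, read 1.56 ± 0.222 against 14.9 ± 0.458 TPM, and the chemokine receptor gene Ccr2 9.88 ± 1.98 against 50.3 ± 0.538 TPM, while Adgre1, which encodes the macrophage protein F4/80, read 30.6 ± 5.53 against 9.89 ± 0.251 TPM. The camera adjusted p were 9.78e-05 for granulocytes and 0.00646 for the monocyte list. With an estimated correlation the adjusted p were 0.248 and 0.188. The monocyte list did not pass without Hif1a-intact replicate 1 (adjusted p = 0.0873) or without Hif1a-null replicate 2 (0.0574). Mast cell, basophil and eosinophil markers, with Cpa3 lower and the eosinophil genes Prg2 and Ear2 higher, did not pass as a list (camera, adjusted p = 0.193); 4 of 8 were higher and 1 lower when adjusted over the list alone. Without Hif1a-null replicate 1 or replicate 2, 0 members of these 3 lists passed. The granulocyte list still passed camera then, with medians of log2 fold change of 0.72 and 0.61 against 0.69 with all libraries; without Hif1a-intact replicate 2 the median was 0.42, with 7 members called.

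Known targets of HIF-1 outside glycolysis were lower. Of 21 measured members 5 fell and 0 rose, with 9 lower when adjusted over the list alone. Egln3 and Egln1, which encode the oxygen-sensing prolyl hydroxylases, fell from 54.1 ± 2.03 to 13.1 ± 0.315 TPM and from 22.3 ± 2.43 to 8.66 ± 0.220 TPM. Ndrg1 fell from 26.1 ± 3.22 to 8.27 ± 0.0882 TPM, and Ak4, a mitochondrial adenylate kinase, from 20.7 ± 0.672 to 4.14 ± 1.84 TPM (n = 2 each). The call of Ak4 was lost in 6 of its 15 alternatives. The fifth, Ddit4, was named after its values were seen (log2 fold change -1.22, limma adjusted p = 0.0342). The list passed camera (adjusted p = 0.000872), but not with an estimated correlation (adjusted p = 0.188). Glucose uptake and glycolysis genes did not pass (camera, adjusted p = 0.101): Pfkm rose (6.23 ± 0.809 against 14.8 ± 0.229 TPM), Pgam1 fell (77.9 ± 0.0797 against 37.0 ± 6.95 TPM, shared with a near-identical copy; its call was lost under either rescaling of the libraries, and its limma adjusted p reached 0.437 over all alternatives), and 19 of 21 were not called, with the same counts when adjusted over the list alone. HIF pathway components did not pass as a list (camera, adjusted p = 0.678); Egln3 and Egln1 are members of it too, and Hif3a rose from 0.907 ± 0.512 to 5.86 ± 0.438 TPM. The median of that list lay above 0 (0.13) and its mean below (-0.03); with 1 library left out the median ran from 0.0039 (without Hif1a-null replicate 1) through 0.076 (without Hif1a-intact replicate 2) to 0.20 (without Hif1a-intact replicate 1). Without Hif1a-null replicate 1 or replicate 2, 0 members of these lists passed. The other HIF-1 targets still passed camera then as a list, with medians of log2 fold change of -0.41 and -0.25 against -0.33 with all libraries.

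**Figure D3:**
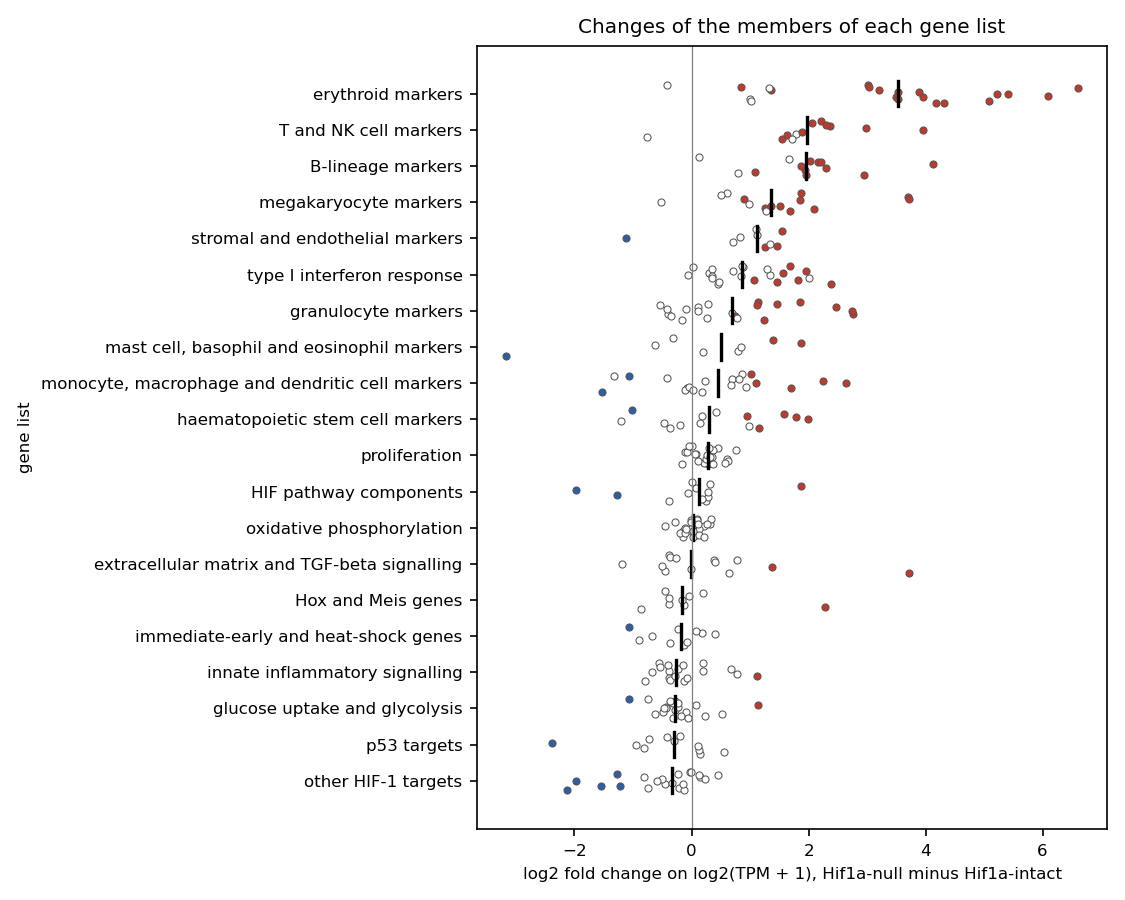
Log2 fold change on the log2(TPM + 1) scale, Hif1a-null minus Hif1a-intact (x axis), of each measured member of the 20 gene lists (y axis). Filled points passed an adjusted p of 0.05 (red higher, blue lower), open points did not, and bars mark list medians, from 3.53 for erythroid markers to -0.33 for other HIF-1 targets.

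Interferon-response genes rose in 7 of 22 members, with 9 when adjusted over the list alone and 13 of 22 called without Hif1a-intact replicate 1. Oas1a rose from 2.79 ± 0.382 to 18.7 ± 0.913 TPM, Oas2 from 0.369 ± 0.108 to 4.33 ± 0.0956 TPM and Usp18 from 2.79 ± 0.157 to 9.48 ± 0.214 TPM (n = 2 each). The list passed camera (adjusted p = 2.57e-09; adjusted p = 0.188 with an estimated correlation). Stromal and endothelial markers rose in 3 and fell in 1 of 9 members, with 7 higher and 1 lower when adjusted over the list alone. With either Hif1a-null library left out, 18 of the 22 interferon and 5 of the 9 stromal members were still tested. The others were under 1 TPM in both Hif1a-intact libraries, so they could only rise. The leptin receptor gene Lepr read 1.23 ± 0.188 against 5.51 ± 0.785 TPM and Sparc 9.25 ± 0.365 against 27.8 ± 7.03 TPM, while Pdgfrb fell from 5.94 ± 1.34 to 2.15 ± 0.0132 TPM (camera, adjusted p = 0.00017; adjusted p = 0.188 with an estimated correlation). Proliferation genes passed camera (adjusted p = 0.00234; adjusted p = 0.188 with an estimated correlation) with no single member called, also when adjusted over the list alone. Of its 23 members 19 lay above 0, with a median log2 fold change of 0.28, or 0.16 without Hif1a-intact replicate 2. Without Hif1a-null replicate 1 or replicate 2, 0 members of these lists passed. All 3 lists still passed camera then, and the median log2 fold change of interferon-response genes was 0.84 and 0.88 against 0.86 with all libraries.

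The other lists did not pass. Stem cell markers had 5 members higher and 1 lower of 14 (camera, adjusted p = 0.0846): Hlf, a stem cell transcription factor, rose from 3.53 ± 1.04 to 14.5 ± 0.940 TPM and Pdzk1ip1 from 1.07 ± 0.318 to 5.18 ± 0.260 TPM, while Gata2 fell from 14.1 ± 0.692 to 6.44 ± 0.332 TPM. Adjusted over the list alone, 7 were higher and 3 lower. Among Hox and Meis genes (camera, adjusted p = 0.481), Pbx3 rose from 0.814 ± 0.345 to 7.77 ± 0.620 TPM and Hoxa10 read 16.6 ± 1.34 and 8.65 ± 1.05 TPM (limma, adjusted p = 0.0535). p53 targets (camera, adjusted p = 0.0943) had Cdkn1a as the 1 member that fell, with 4 lower when adjusted over the list alone, while without Hif1a-intact replicate 1 there were 2 lower and 1 higher, and without replicate 2 there were 3 lower and 0 higher. Innate inflammatory genes (camera, adjusted p = 0.232) had 1 call, Ccl4, which rose. It was lost under quantile normalization and without either Hif1a-intact library. The list itself pointed down, with 13 of 18 members below 0 and a median log2 fold change of -0.26. Adjusted over the list alone, 2 were higher and 4 lower. Immediate-early and heat-shock genes (camera, adjusted p = 0.251) had 1 call, Hspa1b, which fell. That call was lost with another variance model, without a filter and with pseudocounts of 0.1 and 5. Extracellular matrix and TGF-beta genes (camera, adjusted p = 0.321) had 2 calls, Thbs1 and Fn1, both higher. Adjusted over the list alone, 4 were higher and 2 lower, and 7 of the 13 members lay below 0. Oxidative phosphorylation genes (adjusted p = 0.517) had 0 of 25 called. Of the members of these lists, 1 passed without Hif1a-null replicate 1 (Thbs1) and 0 without Hif1a-null replicate 2.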

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

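Robust variance estimation, protein-coding genes only and summed copies were chosen after seeing the data; the other settings were fixed before. No gene called in the comparison changed sign under any setting in which it was tested. Called genes had non-overlapping groups, so this was fixed in advance for other variance models, pseudocounts, filters and left-out libraries. Only settings that rescale values or sum copies could have shown otherwise. Against 866 calls (625 higher, 241 lower), leaving out 1 library gave 0 to 1019 calls, 0 to 731 higher and 0 to 288 lower, with 19 calls (11 higher, 8 lower) without Hif1a-null replicate 1, 0 without Hif1a-null replicate 2 (limma; 958 at an unadjusted p under 0.05), 1019 without Hif1a-intact replicate 1 and 698 without replicate 2. Where an arm kept 1 library, it was assumed to vary like the other group. Without a filter 568 genes were called, 138 of them lower; at 5 TPM or more 493, 332 of them higher; with a pseudocount of 5, 399 higher. Quantile normalization gave 480 higher and 270 lower (64.0% higher).

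With an estimated correlation no list passed: the camera adjusted p was 0.188 for other HIF-1 targets, interferon response, erythroid, monocyte, stromal and proliferation lists, 0.144 for megakaryocyte, B-lineage and T and NK lists, and 0.248 for granulocytes. That setting also leaves only 2 degrees of freedom, so these values do not isolate the effect of correlation. By fry the stem cell (0.0211), p53 (0.0399) and extracellular matrix (0.0122) lists passed, and HIF components pointed down (0.0986). Without a filter glycolysis (0.0287) and stem cell (0.0377) lists passed and Hox genes pointed up (0.698). At 5 TPM or more innate inflammatory genes passed as lower (camera, adjusted p = 0.0157), with a median log2 fold change of -0.37. There the monocyte list did not pass (0.177) and extracellular matrix genes pointed down (0.375). With 1 library left out the adjusted p ranged from 0.0272 to 0.267 for glycolysis (lowest without Hif1a-intact replicate 1), 0.0477 to 0.231 for stem cell markers (lowest without Hif1a-intact replicate 2), 0.00443 to 0.0873 for the monocyte list, 0.125 to 0.586 for oxidative phosphorylation (pointing down without Hif1a-intact replicate 2) and 0.433 to 0.711 for extracellular matrix (pointing down without Hif1a-null replicate 1, 0.653, or 2, 0.711). Apart from those without a filter, at a higher filter or with fewer samples, the cause was not tested.

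Runx1 passed with a pseudocount of 5 (log2 fold change -0.61). In the targeted gene check: Kmt2a ranged from -0.0912 to 0.0126 with 1 library left out, above 0 without Hif1a-null replicate 2. For the similarity of libraries, the mean correlation between groups was 0.965 without a filter, 0.903 at 5 TPM or more, 0.887 and 0.950 with pseudocounts of 0.1 and 5, 0.938 for protein-coding genes and 0.930 to 0.940 with 1 library left out. Among single named genes, 155 of the values under an alternative lost the call and 13 gained one. No paired analysis was possible because the labels give no replicate numbers. Tests made for read counts were not run.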

Other observations

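The tests on Kit, exchanged labels, undeleted exons and large falls in meiosis genes were chosen after their results were seen; those on rescaling, near-identical copies, calls among meiosis genes and the neighbourhood of Hif1a were set before.

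Markers of erythroid, megakaryocyte, B-lineage and T and NK cells were higher together in the Hif1a-null libraries, 46 of them called. Scaling of TPM by abundant genes or pseudogenes was tested by rescaling. All 46 stayed called under median-ratio rescaling and with protein-coding genes only, and 40 under quantile normalization. That fell short of the 9 in 10 set beforehand as arguing against it, so scaling was not excluded by that bound. A common scaling factor would move all genes alike. Before rescaling the median log2 fold change was -0.06 over all tested genes and 3.53 over the 21 erythroid members. Median-ratio rescaling itself sets the median over all genes near 0, and the erythroid median was then 3.56. Those values argue against such a factor as the source of the erythroid rise. All 46 stayed above 0 under each, and their median log2 fold change was 2.30 before and 2.10 after quantile normalization, a comparison added after the result. A lower share of c-Kit-positive cells after selection is a candidate explanation. The log2 fold change of Kit was -0.19 (95% interval -0.60 to 0.21), so it cannot be told apart from a change in the c-Kit-positive cells themselves, which the design names and which was not tested.

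Hif1a TPM was not lower in the libraries labelled Hif1a-null. If the groups were exchanged, targets of HIF-1 should be higher there; instead 6 called members of the target and glycolysis lists were lower and 1 higher (exact two-sided sign test, p = 0.125), and 34 of 42 tested members lay below 0. The direction argues against an exchange, but the test did not reach its bound. That test takes even odds of rising and falling, while 72.2% of all calls were higher, a share that includes genes that could only rise. It also treats the genes as independent, so its p is only a rough guide. Of the 6 called lower, Pgam1 lost its call in 10 of 15 alternatives and Ak4 in 6 of 15. Transcript from undeleted exons may keep the gene value up (log2 fold change 0.28), and with no exon values this cannot be told apart from an undeleted gene.

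Gapdh, usually abundant, read 9.92 to 22.2 TPM. Adding its near-identical copies raised it at least 18.1-fold in every library, consistent with reads shared among pseudogenes. With summed copies the glycolysis list still missed the threshold (camera, adjusted p = 0.148). Summing could move few of its members. Gapdh, Pgk1 and Pgam1 held 5.2%, 20.7% and 47.1% of the TPM summed with their copies, and the other members at least 97.7%.

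Hormad2, Stag3 and Tdrd9 were among the genes that fell most. A hypothesis that meiosis genes in general were lower was tested on a list of 49 others: of the 8 with enough TPM to test, 0 were called lower and 0 higher by limma (5 below 0 and 3 above; at an unadjusted p under 0.05, Syce2 lower and Brdt higher). Beforehand, no more called lower than higher was to count against the hypothesis, but with few members tested and 4% of simulated genes called at a log2 change of 1, such a count can arise either way, so falls of that size stay open. Of simulated changes of 2 and 3, 78% and 88% were called. Those rates hold for genes with a mean log2(TPM + 1) above 2. Members such as Brdt (0.0436 to 2.48 TPM) and Spo11 (0.294 to 2.04 TPM) stood lower. The members ran from -0.74 to 1.18, and in all 6 that stood high enough in the Hif1a-intact libraries to fall by 2 the 95% interval lay wholly above -2, which argues against falls of 2 or more in those members. Only 1 stood high enough to fall as far as Stag3. Calls within 10 Mb of Hif1a, where DNA of another strain could stay linked to the floxed allele, were 7 of 90 genes (7.78%) against 7.27% elsewhere (Fisher's exact test, two-sided p = 0.837), which leaves such linkage open.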
